A study of Mus musculus with 13 samples.

How the data were processed

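The libraries were made from snap-frozen aorta and gastrocnemius muscle of mice aged 88 weeks, in a mixed FVB and C57BL/6 background per the labels. Total RNA was reverse transcribed and amplified with a primer pool that places an amplicon in each targeted transcript, and the products were read on an Ion Torrent sequencer. Such libraries carry no molecular identifiers, so reads are not independent molecules. An amplicon reads a short stretch of its transcript, so a variant under a primer can silence a gene in 1 animal. The labels give 4 groups: aorta Rosa26 (4 libraries), aorta dNdK (2), muscle Rosa26 (4) and muscle dNdK (3). They name no sequencing run, no sex and no doxycycline treatment. By the deposited names, 2 barcode numbers each serve 2 libraries, so there was more than 1 run, and run could not be set against genotype.

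Each of the 13 deposited tables holds raw read counts per gene for 1 library. Per the submitters' processing notes, reads were aligned and counted with STAR 2.5.2b on the mouse genome build mm10 (GRCm38.p6), and edgeR 3.28.1 and limma 3.42.2 were also used. Each deposited table has 3 columns of counts: reads on either strand, then reads on each strand alone. The first of these was used here, since the reads fell on both strands (46.34% to 49.33% on the first strand over the libraries). Of the 19838 genes in each table, 19636 (99%) matched a symbol of the RefSeq annotation of GRCm38.p6, and 2785 had no count in any library. The other 4 lines of each table count unmapped, multimapping, featureless and ambiguous reads. Reads assigned to genes made up 86.66% to 91.42% of each table. No gene of the X or Y chromosome or of mitochondrial DNA is among the genes used here, so such genes were not analysed here.

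Depth was 3919526 to 13683952 gene counts per library. A count of 3, taken as the floor of detection, stood for 0.219 to 0.765 CPM, the counts scaled to library size. Intervals and floors cover counting error only. Where a group of libraries held 0 counts of a gene, the ratio was taken against 3 counts over that group and is given as a lower bound. Where it held 1 to 3 counts, the ratio of pooled CPM is given with its exact 95% counting interval.

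Counts were analysed in R 4.3.3. In each tissue alone, genes were kept by filterByExpr of edgeR 4.0.16 at its default settings (min.count 10, min.total.count 15), scaled by TMM and tested for dNdK against Rosa26 with the edgeR quasi-likelihood test. P-values were adjusted over all genes tested by the method of Benjamini and Hochberg, with a threshold of 0.05. All 13 libraries were fitted together, taken as independent, to test whether the genotype effect differed between the tissues. Log2 fold changes come from these fits. The standard error (SE) of a gene was derived from its test, as the absolute log2 fold change over the square root of the quasi-likelihood F. Group means with their standard deviations (SD) are TMM-scaled CPM. Marker levels of single libraries are plain CPM.

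Gene lists of cell types, pathways and quality markers were fixed before the data were examined, 39 in number, of which 1 had no measured member. Lists with at least 5 measured members were tested on log2 CPM (prior count 2) with camera of limma 3.58.1, a test of a list against all other genes, at its preset inter-gene correlation of 0.01. Adjustment ran over the lists of each comparison. Beside it stand camera with the correlation estimated for each list, and fry, which asks whether the members move on balance 1 way. The number of members past the threshold was counted over all genes tested and adjusted over the list alone. The score of a list in a library is the mean difference of its members' log2 CPM from their mean over the tissue.

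The genes named in the text follow a rule that was also fixed. It takes Foxm1 first. Unnamed predicted genes are counted but not named. It then takes up to 10 genes in each direction past the threshold with groups that did not overlap and a mean log2 CPM of at least 3, or the 5 with the smallest p where fewer than 5 passed. It adds up to 4 members of each list that camera called, the 3 members with the smallest p of 3 lists on FOXM1, senescence and secreted factors, 5 set genes (Cdkn1a, Cdkn2a, Ccnb1, Mki67, Il6), and the 5 genes with the smallest p for a difference between the tissues. Marker genes named for the make-up of single libraries, and Gpr157, H2-Aa and the genes on or off in single animals, were chosen after their values were seen.

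The pipeline was tested on simulated data with known changes. At 4-fold it called 55.7% of changed genes in the aorta design, 67.2% in the muscle design and 23.1% for a difference between the tissues, and at 2-fold 3.39%, 9.86% and 0%. Of 11400, 10116 and 11817 unchanged genes it called 12, 7 and 1. The simulated genes were independent, so the lists' test was not tried on correlated genes. The simulated libraries held no differences in make-up within a genotype, so these false calls need not hold for the real libraries. Alternatives were other scalings, filters, tests (DESeq2 1.42.0, limma-voom) and strand columns, a block on the number in the titles, and leaving out each library in turn. Others were chosen after the data were seen: leaving out libraries with RNA of other tissues, scores of cell types as covariates, and leaving out genes that are on or off in single libraries.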

Results

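Gene counts were measured in 6 aorta and 7 gastrocnemius libraries of 88-week-old mice (1.7 years), with an amplicon panel for the mouse transcriptome. Control mice, called Rosa26 here, carried Rosa26-rtTA, a gene for the doxycycline-controlled transactivator. The other genotype, called dNdK, carried GFP-FOXM1dNdK, a GFP-tagged form of the cell cycle transcription factor FOXM1, beside it. The aorta libraries Rosa26 1 to 4 held 9735426, 12399087, 9880325 and 3919526 gene counts, and dNdK 1 and 2 held 8578272 and 10701658. The muscle libraries Rosa26 1 to 4 held 7436030, 11760384, 13123246 and 10728698 gene counts, and dNdK 1 to 3 held 6792153, 10641374 and 13683952. The numbers run within each tissue and do not pair the animals. The series asks what more FOXM1 activity does in aged tissue, and the comparisons below set dNdK against Rosa26 in each tissue and then the tissues against each other.

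The make-up of the libraries differed within genotypes. Ucp1, the uncoupling protein of brown fat, stood at 5530 to 10100 CPM in all 6 aorta libraries, and Adipoq, an adipocyte hormone, at 135 to 202 CPM. There Myh11, a smooth muscle myosin, stood at 71.9 to 103 CPM and Acta2, a smooth muscle actin, at 83.5 to 359 CPM. In the muscle libraries Myh11 stood at 22.5 to 68.9 CPM and Acta2 at 36.7 to 105 CPM, so these 2 were little higher in aorta. Tagln, of the smooth muscle list, stood at no more than 0.0807 CPM in aorta. Cnn1 and Eln, of the smooth muscle and matrix lists, reached 16.2 and 60.6 CPM in aorta, against at most 4.79 and 14.4 CPM in muscle. The aorta results below are thus of fat and vessel wall together, in shares that were not measured, and were not split between them. Myh6, the main myosin of adult mouse heart, stood at 911, 394 and 685 CPM in aorta Rosa26 1, Rosa26 2 and dNdK 2, and at 0 to 2.13 CPM in the other 3 aorta libraries. In muscle, Myh4, the fast fibre myosin, stood at 30000 to 42900 CPM in all 7 libraries. Adipoq stood at 129 CPM and Ucp1 at 701 CPM in muscle dNdK 3, against at most 6.89 and 5.89 CPM in the other 6.

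**Figure D1:**
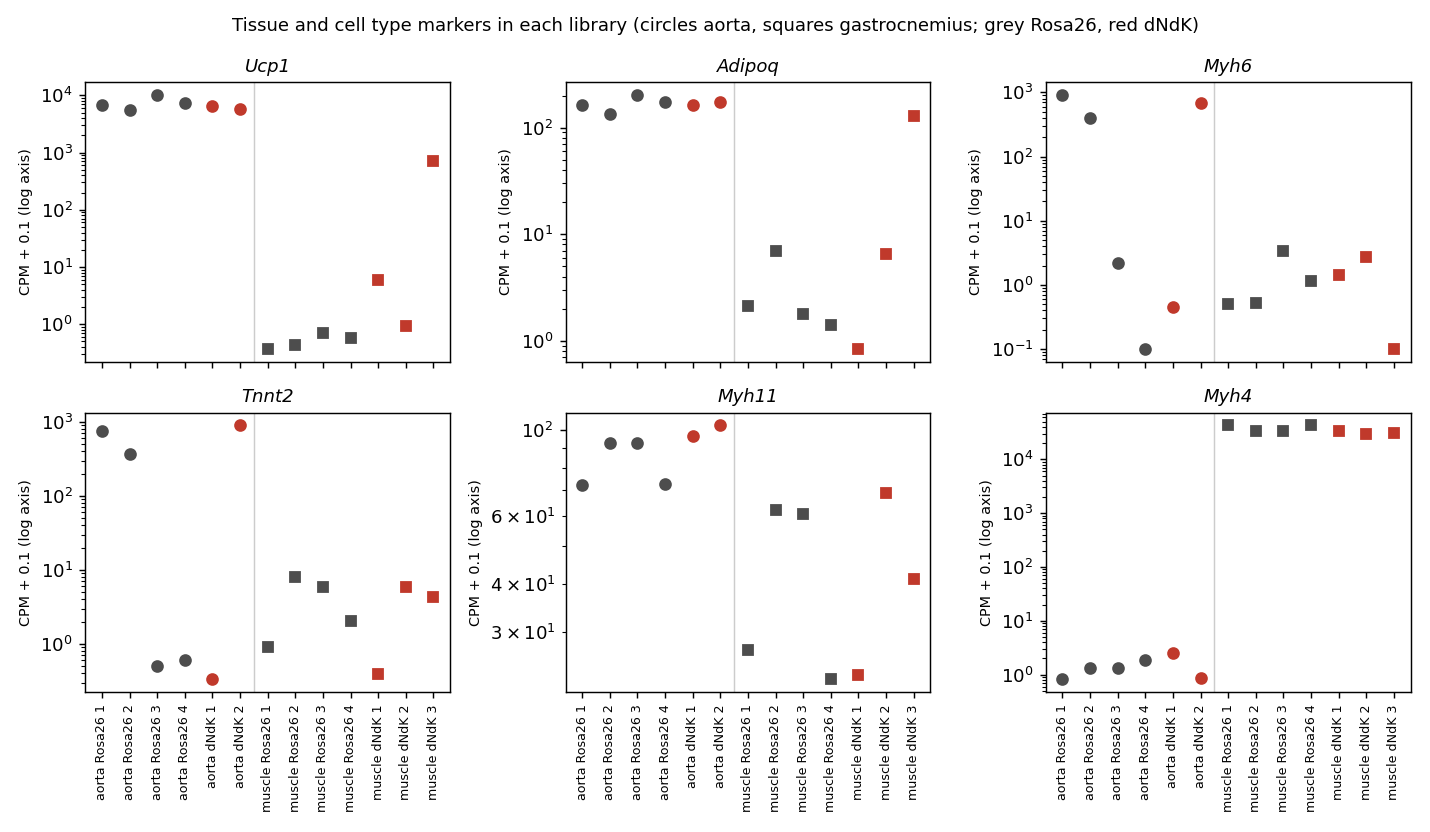
CPM (log axis, 0.1 added) of 6 marker genes in each of the 13 libraries, with circles for aorta, squares for gastrocnemius, grey for Rosa26 and red for dNdK. Myh6 lies at 394 to 911 CPM in 3 aorta libraries, 2 Rosa26 and 1 dNdK, and Adipoq reaches 129 CPM in 1 muscle library, dNdK 3.

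Foxm1 itself was close to the floor of detection in both tissues. In aorta its counts were 3, 24, 13 and 2 in Rosa26 1 to 4 and 2 and 5 in dNdK 1 and 2. Its mean was 0.963 ± 0.669 CPM (SD, n = 4) in Rosa26 and 0.372 ± 0.175 CPM (n = 2) in dNdK, a log2 fold change of −1.38 (SE 0.96) that did not pass the edgeR test (adjusted p = 0.763). In muscle every library held 0 to 3 counts of Foxm1, too few to be tested. Whether the mouse amplicon reads the FOXM1 transgene is not stated in the labels, so these counts do not check its expression.

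In dNdK aorta the genes of mitosis, of antigen presentation by MHC class II and of mast cells were lower as groups, and 1 single gene rose. That gene was Ube2ql1, a ubiquitin-conjugating enzyme gene on chromosome 13 (69702832 to 69739897, GRCm38.p6). It stood at 9.66 ± 1.16 CPM in Rosa26 (SD, n = 4) and 77.5 ± 4.38 CPM in dNdK (n = 2), 7.97-fold higher (log2 fold change 2.99, SE 0.22, edgeR adjusted p = 0.00779). All 40 measured members of the FOXM1 and G2/M list, which drive chromosome segregation and cell division, had lower estimates in dNdK, with a median log2 fold change of −1.58 (camera adjusted p = 3.21e-13). The 11 measured members of the MHC class II list did so too, with a median of −1.82 (adjusted p = 3.92e-06). These 2 calls and that of the mast cell list, given below, were lost with an estimated correlation (adjusted p = 0.734 for each list).

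The mitotic genes were low in number of reads, and their estimates had 1 direction as a contrast of the groups, not library by library. The FOXM1 and G2/M score was −0.84 in Rosa26 4, between −0.56 in dNdK 1 and −1.08 in dNdK 2. Top2a, the topoisomerase that untangles chromosomes, stood at 8.94 ± 5.94 CPM in Rosa26 and 0.881 ± 0.685 CPM in dNdK (log2 fold change −3.38, SE 0.89), without passing the edgeR test (adjusted p = 0.757, as for each aorta gene below with no p of its own). Birc5, the survivin gene, had a log2 fold change of −2.75 (SE 0.75), Ccnb2, a mitotic cyclin, −3.10 (SE 0.84), and Aspm, a spindle pole gene, −2.99 (SE 0.88). Mki67, the gene of the proliferation antigen Ki-67, had −1.60 (SE 0.99) but turned to 0.182 without Rosa26 1 and 2, 0.264 without the 3 libraries with heart RNA, and 0.552 and 0.906 with the B and the T cell score as a covariate. Ccnb1, cyclin B1, had at most 3 counts in any aorta library and was not tested. Of the list's 40 members 0 passed the test over all genes, 0 adjusted over the list alone, and 14 had an unadjusted p under 0.05, all lower. The median was −1.47 without the 3 members that had a group with at most 3 counts. The DNA replication list, the genes that copy DNA in S phase, had 27 of 30 estimates lower and a median of −0.77 (camera adjusted p = 2.69e-05, and adjusted p = 0.734 with an estimated correlation). Among its members Tk1, thymidine kinase, had −2.50 (SE 0.68), Pold1, a replicative polymerase, −1.17 (SE 0.34), and Mcm5 and Mcm4, subunits of the replicative helicase, −1.86 (SE 0.65) and −0.88 (SE 0.34). The FOXM1 and G2/M score ran with the B and plasma cell score across libraries. The latter was 1.72 and 3.15 in Rosa26 1 and 2, 0.41 and −3.01 in Rosa26 3 and 4, and −0.61 and −1.65 in dNdK 1 and 2. Without Rosa26 1 and 2 the FOXM1 and G2/M list was no longer called (median −0.41, camera adjusted p = 0.249). Neither was the DNA replication list (median −0.27, camera adjusted p = 0.148). That setting kept only Rosa26 3 and 4 as controls, which also stood apart in their share of unmapped reads, given below. The DNA replication score was as low in Rosa26 4 (−0.408) as in dNdK 1 and 2 (−0.397 and −0.39).

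In dNdK aorta the MHC class II, mast cell, T and NK cell and B and plasma cell lists were lower by camera at its preset correlation. The macrophage and monocyte list, given below, was lower too. In each of these lists 0 members passed over all genes. The neutrophil list was not called (adjusted p = 0.124). Within the MHC class II list, whose products present antigen to helper T cells, 4 members were lower when adjusted over the list alone and 0 over all genes. H2-Ab1 stood at 90.7 ± 53.8 CPM in Rosa26 and 24.5 ± 3.73 CPM in dNdK, Cd74, the invariant chain, had a log2 fold change of −1.77 (SE 0.56), Ciita, the regulator of the group, −1.82 (SE 0.55), and H2-DMb2 −2.48 (SE 0.74). H2-Aa, another member, stood at 160 CPM in aorta Rosa26 3 and at 0.0934 to 1.37 CPM in the other 5 aorta libraries. The mast cell list had 6 of 7 estimates lower and a median of −1.60 (camera adjusted p = 0.000152, and adjusted p = 0.734 with an estimated correlation), and 5 members were lower when adjusted over the list alone. Its proteases had log2 fold changes of −2.04 (SE 0.41, Mcpt4), −1.61 (SE 0.41, Cpa3), −1.60 (SE 0.47, Cma1) and −1.42 (SE 0.43, Tpsb2). All 21 T and NK cell genes and all 14 B and plasma cell genes had lower estimates, with medians of −1.71 and −3.29 (camera adjusted p = 1.26e-05 and 0.00928). Their adjusted p were 0.734 and 0.768 with an estimated correlation. Rosa26 4 lay below both dNdK libraries in both scores (−1.451 against −0.684 and −0.822 for T and NK cells). Examples are Cd8b1, a coreceptor of killer T cells (−2.81, SE 0.95), Cd28, a T cell costimulatory receptor (−2.02, SE 0.69), Blk, a B cell kinase (−4.55, SE 1.72), and Pax5, the B lineage factor (−3.30, SE 1.34). Gzma, a granzyme of killer cells, had 74 counts in Rosa26 and 1 in dNdK, a ratio of 39.7 (95% counting interval 6.91 to 1590). It stood at 0 CPM in Rosa26 4, so its groups overlapped. Without Rosa26 1 and 2 neither lymphocyte list was called (medians −0.22 and −0.84, adjusted p = 0.588 and 0.977), and the B and plasma cell test changed sign. That list was also not called without Rosa26 1, Rosa26 2 or dNdK 2 alone (adjusted p = 0.0999, 0.132 and 0.124). Without Rosa26 1 and 2 the MHC class II and mast cell lists stayed lower (medians −1.11 and −1.31, adjusted p = 0.0309 for each). Over the 6 libraries the B and plasma cell score had a Pearson r of 0.806 with the MHC class II score (exact permutation p = 0.0569, adjusted 0.0854 over 3 relations) and of 0.478 with the mast cell score (p = 0.338, adjusted 0.338). Spearman rho was 0.771 and 0.6 (adjusted p = 0.154 and 0.242), and r without Rosa26 2 and 4 was 0.741 and 0.924.

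Macrophage, interferon and inflammation lists were also lower in dNdK aorta. The macrophage and monocyte list had 24 of 26 estimates lower (median −0.67, camera adjusted p = 2.31e-05), the interferon response list 33 of 34 (median −0.69, adjusted p = 9.96e-06), the NF-kB inflammation list 20 of 26 (median −0.79, adjusted p = 0.00026) and the SASP list, secreted factors of senescent cells, 31 of 39 (median −0.64, adjusted p = 0.00575). None of these 4 was called with an estimated correlation (adjusted p = 0.734 for each), and in each 0 members passed when adjusted over the list alone. The interferon response score was −0.662 in Rosa26 4, below dNdK 1 and 2 (−0.289 and −0.461). Itgam, an integrin of myeloid cells, had a log2 fold change of −1.98 (SE 0.54), Tyrobp, its signalling adaptor, −1.01 (SE 0.33), and Parp14 and Psmb8, interferon-induced genes, −0.92 (SE 0.27) and −1.07 (SE 0.36). Selp, the P-selectin that captures leukocytes, had −1.83 (SE 0.48), Nfkb2 −0.82 (SE 0.25), Tnfrsf11b, the decoy receptor osteoprotegerin, −2.16 (SE 0.56), and Icam1 −0.86 (SE 0.37). Il1b, the interleukin 1 beta gene, had 43 counts in Rosa26 and 2 in dNdK, a ratio of 11.5 (95% counting interval 3.01 to 98.3). Without Rosa26 1 and 2, the libraries with the highest B and plasma cell scores, the macrophage and interferon lists were no longer called (adjusted p = 0.222 and 0.283). The SASP list was not called without the 3 libraries with heart RNA (adjusted p = 0.0517), nor with the B or the T cell score as a covariate (0.129 and 0.202). In the same 3 settings the macrophage list had adjusted p = 0.79, 0.0715 and 0.202 and the interferon list 0.635, 0.16 and 0.586. The macrophage median was −0.44 without dNdK 2 and the SASP median −0.42 without Rosa26 3. The endothelial list had 19 of 23 estimates lower (median −0.50, camera adjusted p = 0.00689), with Vwf, the von Willebrand factor, at −1.08 (SE 0.44) and Icam2 at −1.12 (SE 0.38). The immediate early and dissection stress list had 19 of 25 lower (median −0.48, adjusted p = 0.0458), with the heat shock gene Hspa1b at −1.96 (SE 0.64) and Myc at −1.43 (SE 0.53). These had adjusted p = 0.742 and 0.768 with an estimated correlation. Without Rosa26 3 or without Rosa26 4 neither was called (adjusted p up to 0.128 and 0.575), and without dNdK 2 the immediate early list was not called either (adjusted p = 0.0875).

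In dNdK aorta 3 lists were slightly higher. The oxidative phosphorylation list, the respiratory chain, had 40 of 50 estimates higher (median 0.22, camera adjusted p = 0.000237), the proteasome list 19 of 28 (median 0.19, adjusted p = 0.00641) and the white adipocyte list 24 of 29 (median 0.24, adjusted p = 0.00158). With an estimated correlation the adjusted p was 0.734 for each, and 0 members passed when adjusted over each list alone. Sdhc, a subunit of succinate dehydrogenase, had a log2 fold change of 0.57 (SE 0.22), Psma4, of the proteasome core, 0.54 (SE 0.24), Slc2a4, the insulin-responsive glucose transporter, 0.87 (SE 0.27), and Acaca, the first enzyme of fatty acid synthesis, 1.05 (SE 0.38). Scd1, a fatty acid desaturase, stood at 10200 to 44200 CPM in Rosa26 and at 34900 and 46500 CPM in dNdK, a spread within Rosa26 as wide as the difference. The white adipocyte call was lost without dNdK 1 (adjusted p = 0.117) and the proteasome call without dNdK 2 (adjusted p = 0.0657). The white adipocyte median was 0.48 without Rosa26 4, and the proteasome median 0.09 without Rosa26 3. Without the 3 libraries with Myh6 at 394 to 911 CPM none of the 3 lists was called (adjusted p = 0.0672 for oxidative phosphorylation and proteasome, 0.325 for white adipocyte). The p53 targets and senescence list was not called (adjusted p = 0.621, test higher but median −0.03 and mean −0.02). Of its members, Cdkn1a, the p21 cell cycle inhibitor, stood at 58.2 ± 7.22 CPM in Rosa26 and 97.2 ± 29.3 CPM in dNdK (log2 fold change 0.74, SE 0.25), Gadd45b had 1.06 (SE 0.48) and Cdkn2a, the p16 and p19 locus, −1.61 (SE 0.80). Il6, the interleukin 6 gene, was too low to be tested in either tissue.

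**Figure D2:**
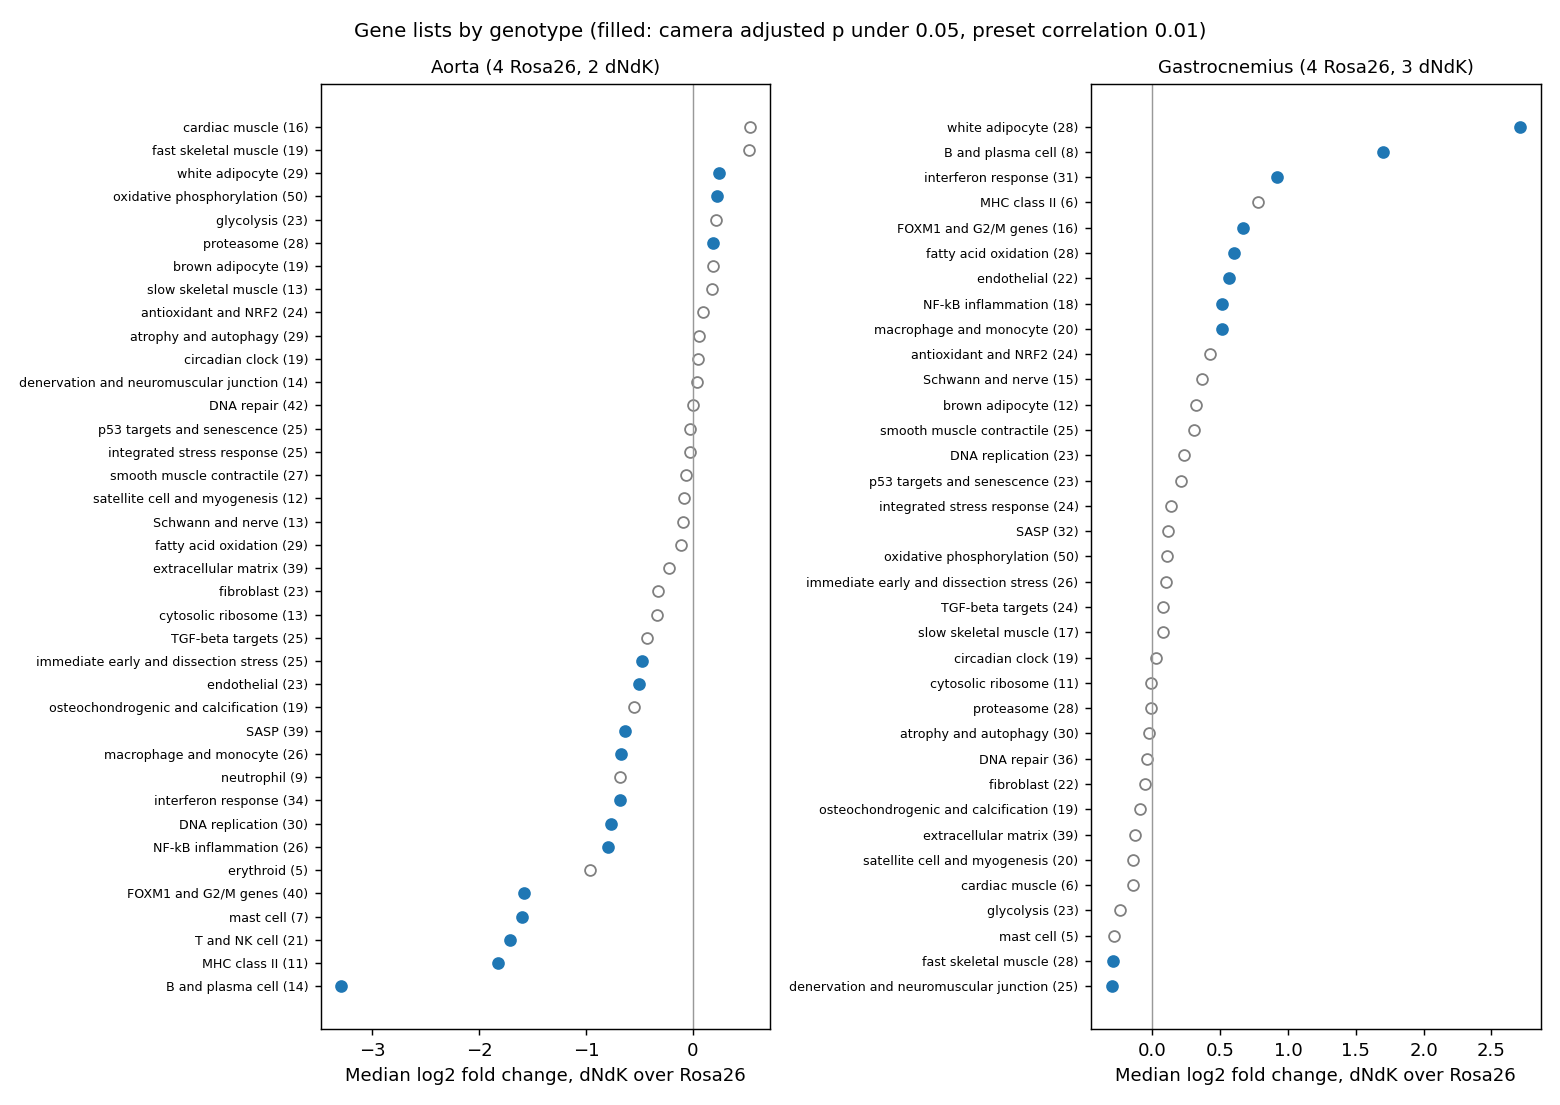
Median log2 fold change of each tested gene list, dNdK over Rosa26, with the number of measured members in brackets and filled points for lists called by camera at its preset correlation. In aorta 12 lists lie lower and 3 higher, in gastrocnemius 2 lower and 8 higher, and with an estimated correlation 0 lists were called in either tissue.

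Of 11920 aorta genes tested with edgeR, 1 was higher and 0 lower in dNdK at an adjusted p under 0.05, and 713 had an unadjusted p under 0.05 (278 higher, 435 lower, 596 expected by chance). DESeq2 called 13 aorta genes, 9 higher and 4 lower, among them Ube2ql1, C7, Ptgds, Mcpt4 and Top2a. The edgeR count depended on the setting: 264 without Rosa26 1 and 2, 163 with a block on the number in the titles, and 0 with all 13 libraries in 1 fit. The groups did not overlap for 2067 genes (17.3%), where chance gives 13.3%. C7, a complement component, stood at 8.98 ± 3.78 CPM in Rosa26 and 39.5 ± 3.73 CPM in dNdK (log2 fold change 2.17, SE 0.37), and Ptgds, prostaglandin D2 synthase, had 1.36 (SE 0.25). Tmem82 and Slc25a34, a mitochondrial carrier, had −2.37 (SE 0.50) and −2.20 (SE 0.48). Zfp729b, a zinc finger gene, had 0 counts in Rosa26 and 62 in dNdK, at least 38.5-fold higher, and Rsl1, another, had 2 and 52 counts, a ratio of 48.5 (95% counting interval 12.8 to 411). In muscle, however, they had 28 and 15 counts in Rosa26 2, 16 and 18 in dNdK 3, and 0 in dNdK 1 and 2. There their state did not follow the genotype. Esco2, a cohesin acetyltransferase, had 69 counts in Rosa26 and 2 in dNdK, a ratio of 18.5 (4.93 to 156), and Faim2, an inhibitor of cell death, 114 and 1, a ratio of 61.2 (10.8 to 2440). With the counts of either strand alone Ube2ql1 kept its direction but not its call (adjusted p = 0.316 and 0.841), as without Rosa26 1, Rosa26 2, dNdK 1 or dNdK 2 (0.103, 0.0539, 0.259 and 0.0898). Over its 23 alternatives it was called in 16, with log2 fold changes of 2.75 to 3.21 and adjusted p from 3.02e-21 to 0.841. Among the 16 is the earlier quasi-likelihood of edgeR, which repeated the main fit (log2 fold change 2.99, adjusted p = 0.00779) and is no separate check.

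**Figure D3:**
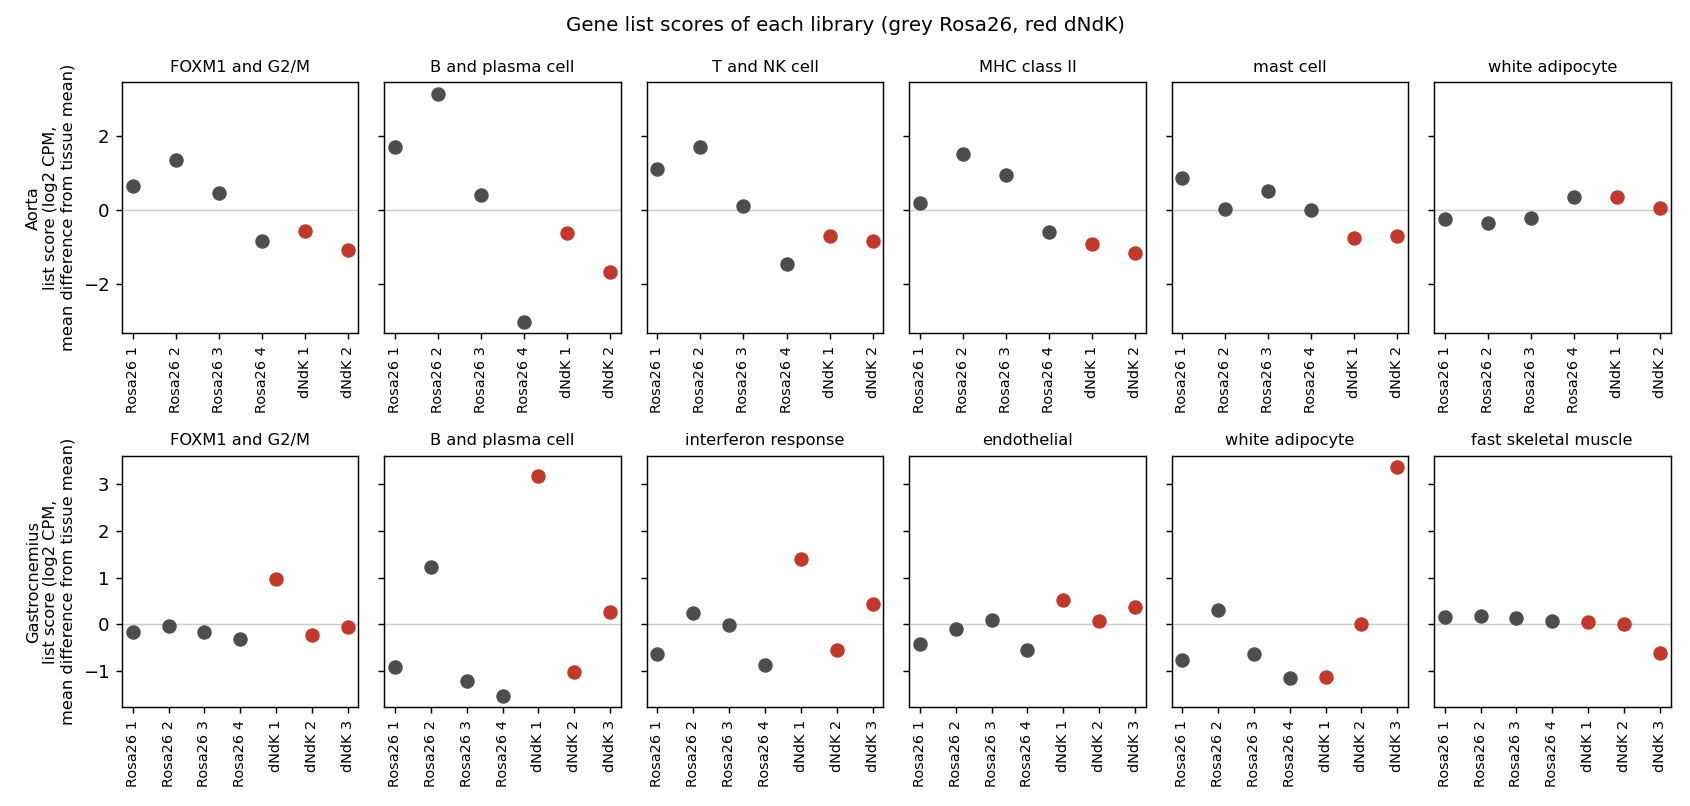
Score of 6 gene lists in each aorta library (top) and each gastrocnemius library (bottom), as the mean difference in log2 CPM from the tissue mean, grey for Rosa26 and red for dNdK. In aorta the FOXM1 and G2/M score runs with the B and plasma cell score, and in muscle the white adipocyte score of 3.35 belongs to dNdK 3 and the B and plasma cell score of 3.17 to dNdK 1.

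In dNdK muscle the lists of endothelial cells and fatty acid oxidation were higher and that of fast fibres was lower, while no single gene passed the test. Of 22 endothelial genes 21 had higher estimates, with a median log2 fold change of 0.56 (camera adjusted p = 1.84e-06). Over 14 alternatives this median ran from 0.287 to 0.7. Of 28 fatty acid oxidation genes 26 were higher in estimate (median 0.60, adjusted p = 1.64e-05). Of 28 fast skeletal muscle genes 27 had lower estimates (median −0.29, adjusted p = 4.65e-06). With an estimated correlation none of these 3 was called (adjusted p = 0.607 for each), and in each 0 members passed when adjusted over the list alone. Gpihbp1, the capillary anchor of lipoprotein lipase, stood at 36 ± 4.07 CPM in Rosa26 (SD, n = 4) and 64.7 ± 19.7 CPM in dNdK (n = 3), a log2 fold change of 0.85 (SE 0.24, edgeR adjusted p = 0.656, as for each muscle gene below with no p of its own). Nos3, the endothelial nitric oxide synthase, had 1.08 (SE 0.33), Plin5, a lipid droplet coat protein of muscle, 1.18 (SE 0.28), and Slc25a20, the mitochondrial carnitine carrier, 0.76 (SE 0.23). Cacng1 and Cacna1s, subunits of the muscle calcium channel, had −0.54 (SE 0.20) and −0.59 (SE 0.24). The fast fibre score was 0.08 to 0.18 in Rosa26, 0.05 and 0.01 in dNdK 1 and 2 and −0.61 in dNdK 3, the library with Adipoq at 129 CPM, and the call was lost without that library (adjusted p = 0.0783). The fatty acid oxidation score was −0.393 to −0.086 in Rosa26, −0.096 and 0.168 in dNdK 1 and 2 and 0.831 in dNdK 3, and without dNdK 3 the list had a median of 0.25 (adjusted p = 0.00885).

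Some muscle lists rested on single libraries. The white adipocyte list had 27 of 28 estimates higher in dNdK and a median of 2.71 (camera adjusted p = 1.54e-05, and adjusted p = 0.612 with an estimated correlation), and 20 members were higher when adjusted over the list alone. Thrsp, a switch of fat synthesis, stood at 29.7 ± 4.15 CPM in Rosa26 and 725 ± 1210 CPM in dNdK, Fabp4, the fatty acid carrier of fat and capillaries, had a log2 fold change of 2.98 (SE 0.89) and Lep, leptin, 4.17 (SE 1.31). In 27 of the 28 members dNdK 3 was the highest library, and without it the median was 0.14 and the list was not called (adjusted p = 0.938), while without dNdK 1 and 3 it was 0.33 (adjusted p = 0.00823). The interferon response list had 27 of 31 estimates higher (median 0.92, camera adjusted p = 7.52e-05), the B and plasma cell list 8 of 8 (median 1.70, adjusted p = 0.0151), the NF-kB inflammation list 14 of 18 (median 0.51, adjusted p = 0.0307) and the FOXM1 and G2/M list 13 of 16 (median 0.67, adjusted p = 0.0369). With an estimated correlation their adjusted p were 0.612, 0.612, 0.607 and 0.607, and in each 0 members passed when adjusted over the list alone. Cxcl9, a chemokine that interferon induces, had 3.39 (SE 0.95), Jchain, the joining chain of secreted antibodies, 3.46 (SE 1.01), Vcam1, an adhesion molecule, 1.35 (SE 0.55), Mad2l1, a spindle checkpoint gene, 1.05 (SE 0.45), and Top2a 2.47 (SE 1.20, adjusted p = 0.662), while Aurka, a mitotic kinase, had −1.26 (SE 0.59, adjusted p = 0.657). The B and plasma cell score was 3.17 in dNdK 1 and at most 1.22 in the other 6 muscle libraries, and without dNdK 1 none of these 4 lists was called (adjusted p of 0.572 to 0.763). The FOXM1 and G2/M list was also not called without any 1 of the 4 Rosa26 libraries (adjusted p of 0.0502 to 0.116), the NF-kB inflammation list without Rosa26 2 or 3 (0.0843 and 0.093) and the B and plasma cell list without Rosa26 3 or 4 (0.0669 and 0.0567). The macrophage and monocyte list had 15 of 20 estimates higher (median 0.51, camera adjusted p = 0.00132, and adjusted p = 0.612 with an estimated correlation), with C1qb, a complement gene of macrophages, at 1.14 (SE 0.48). Its median ran from 0.27 without dNdK 3 to 0.94 without Rosa26 2, and without dNdK 1 and 3 it was not called (median −0.07, adjusted p = 0.875).

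The denervation and neuromuscular junction list was lower in dNdK muscle, with 17 of 25 estimates lower and a median of −0.30 (camera adjusted p = 0.0147, and adjusted p = 0.607 with an estimated correlation), and 0 members passed when adjusted over the list alone. It was not called without Rosa26 2 (adjusted p = 0.0958) or without dNdK 2 (adjusted p = 0.266), and its median was −0.16 without Rosa26 1. Actc1, the heart and fetal muscle actin, stood at 624 ± 159 CPM in Rosa26 and 209 ± 123 CPM in dNdK (log2 fold change −1.58, SE 0.43), and Mybph, a myosin-binding protein, had −0.96 (SE 0.52, adjusted p = 0.698). The p53 targets and senescence list and the SASP list were not called in muscle (adjusted p = 0.779 and 0.684). Fas, a death receptor, had 1.10 (SE 0.52, adjusted p = 0.661), Cdkn1a had 0.56 (SE 0.77, adjusted p = 0.896), Cdkn2a, Mki67 and Ccnb1 were too low to be tested, and Ccl8 and Ccl7, monocyte chemokines, had 3.81 (SE 1.13) and 2.49 (SE 0.80).

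Of 10491 muscle genes tested with edgeR, 0 passed at an adjusted p under 0.05, and 792 had an unadjusted p under 0.05 (570 higher, 222 lower, 524.6 expected by chance), while DESeq2 called 7 and limma-voom 0. The groups did not overlap for 623 genes (5.94%), where chance gives 5.71%. Among the genes with the smallest p, Mxra8, a matrix remodelling receptor, stood at 129 ± 16 CPM in Rosa26 and 57.4 ± 9.48 CPM in dNdK (log2 fold change −1.17, SE 0.21), and Ostn, the muscle hormone musclin, at 219 ± 76 and 71.4 ± 23.6 CPM (−1.62, SE 0.33). Rbm24, a muscle splicing factor, had −1.21 (SE 0.23), Ntn4, a netrin, −1.23 (SE 0.26), and Tmc7 −1.08 (SE 0.24). On the higher side Cops8, a subunit of the COP9 signalosome, stood at 88.1 and 60.5 CPM in dNdK 2 and 3 but at 0.147 CPM in dNdK 1 and at most 0.935 CPM in Rosa26. Apobec3, an antiviral deaminase, had 2.23 (SE 0.48), Rtraf, a factor of RNA transcription and transport, 2.23 (SE 0.52), Sh3d21 2.36 (SE 0.54) and Stk39, a kinase of salt transport, 1.58 (SE 0.37). Without dNdK 1 edgeR called 3 muscle genes, Cops8, Gpr157 and Rtraf. Like Cops8, the other 2 were high in dNdK 2 and 3 alone. Rtraf stood there at 58.5 and 67.5 CPM and at 8.54 CPM in dNdK 1, and Gpr157 at 26.4, 13.4 and 0.147 CPM. In aorta Cops8, Rtraf and Gpr157 stood at 61.2, 33.2 and 3.61 CPM in dNdK 1 but at 0.374, 10.2 and 0.28 CPM in dNdK 2. These genes thus differed between libraries of the dNdK genotype.

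**Figure D4:**
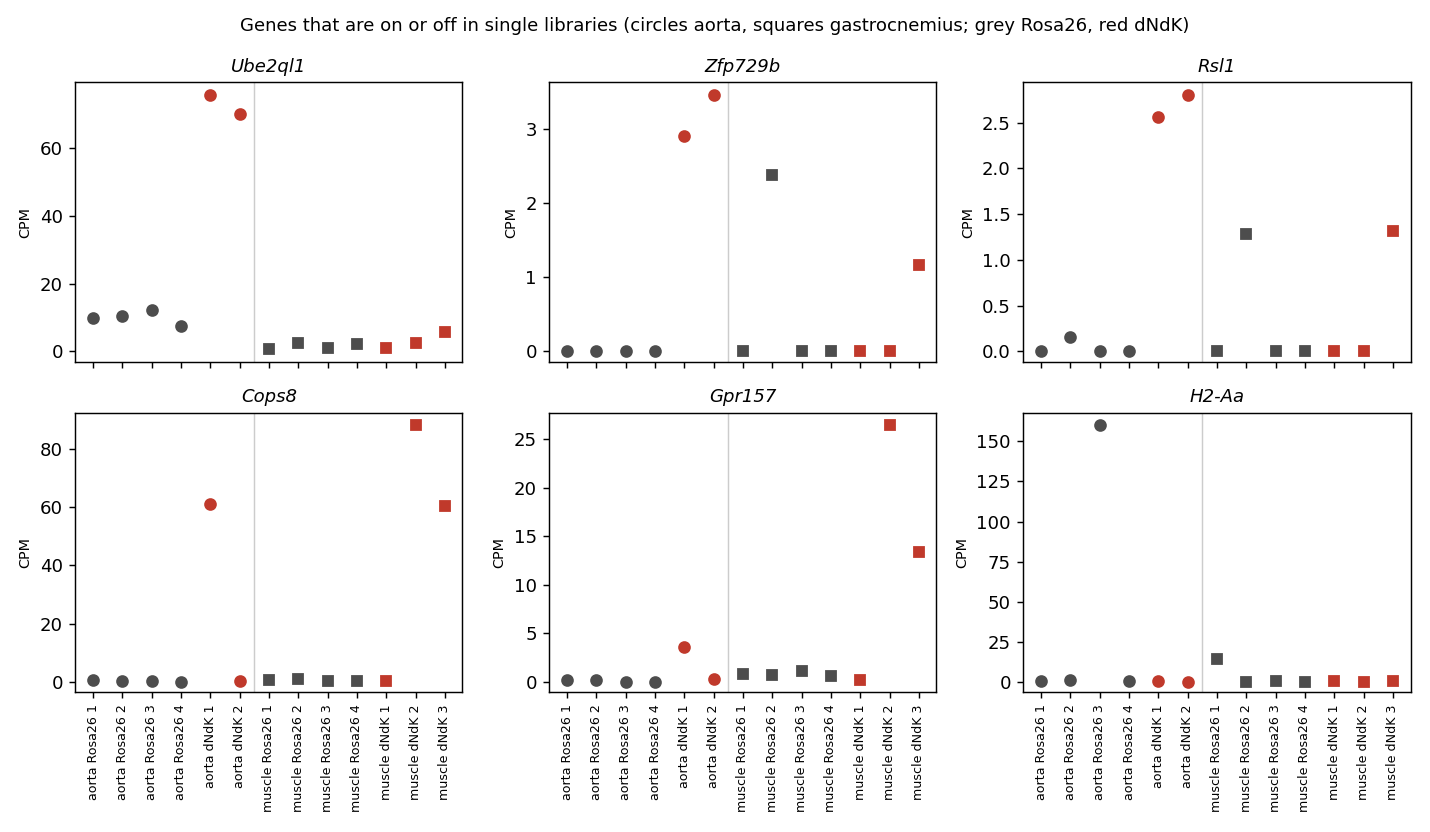
CPM of 6 genes in each of the 13 libraries, with circles for aorta, squares for gastrocnemius, grey for Rosa26 and red for dNdK. Cops8 lies at 61.2 CPM in aorta dNdK 1 and at 88.1 and 60.5 CPM in muscle dNdK 2 and 3, and below 1 CPM in the other 10 libraries.

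The genotype effect was then compared between the tissues. The FOXM1 and G2/M list was lower in dNdK aorta and higher in dNdK muscle, and the difference of the effects had a median of −2.73 over 41 members (camera adjusted p = 4.57e-12, and adjusted p = 0.464 with an estimated correlation). In the fit of muscle by itself 16 of its members were measured, and there the call was lost without dNdK 1 (adjusted p = 0.763). The interferon response (−1.67, adjusted p = 2.93e-07) and endothelial lists (−1.11, adjusted p = 9.46e-08) also had lower estimates in aorta and higher ones in muscle. For the T and NK cell list, of which 3 members were measured in the fit of muscle by itself, the median difference was −3.64 (adjusted p = 1.75e-07). With an estimated correlation the adjusted p was 0.464 for each of these 3 as well. Of 38 lists 19 were called, 15 of them more negative in aorta and 4 more positive, and 0 with an estimated correlation. This fit takes the libraries as independent, although 4 file numbers recur in both tissues. For fast skeletal muscle genes the median was 0.40 and the test positive (adjusted p = 0.0356, and adjusted p = 0.576 with an estimated correlation), but the mean was −0.01. Of 12318 genes tested with edgeR for a difference, 0 passed, 1044 had an unadjusted p under 0.05, DESeq2 called 6 and limma-voom 0. The genes with the smallest p were Fam57b (difference in log2 fold change 1.84, SE 0.35), Ptbp3, a splicing regulator (−1.77, SE 0.36), Sorbs3, the adaptor vinexin (1.27, SE 0.28), Epm2aip1 (1.33, SE 0.30) and Tmc7 (2.23, SE 0.51), with an edgeR adjusted p of 0.583 for each. Across the 10254 genes tested in both tissues, which are not independent replicates, the log2 fold changes had a Pearson r of −0.063 and a Spearman rho of −0.071, and 47.6% had the same sign.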

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

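The depth thinning below was set before its result was seen, and the other tests of this part were chosen only after the results were seen.

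Values of single Rosa26 libraries stood apart from the other 3 of their group in 7 of 110 groups examined, where chance gives about 1 in 20. The measure is the gap to the nearest library over the whole range of the 4. In aorta it was 0.832 for Esco2 (higher in Rosa26 1), 0.888 for Gadd45b (higher in Rosa26 4), 1 for Rsl1 (2 counts in Rosa26 2, none in the others), 0.958 for Gzma (lower in Rosa26 4), 0.931 for Cox6c, a respiratory chain gene (lower in Rosa26 3), and 0.833 for the score of the proteasome list (lower in Rosa26 3). In muscle it was 0.876 for Trp53inp1, a p53 target (lower in Rosa26 3).

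The genotype effect differed between the tissues for 19 lists by camera at its preset correlation, and for 0 with an estimated correlation (adjusted p from 0.464 to 0.817 over the 19). The median differences, aorta minus muscle on the log2 scale, were −2.732 for FOXM1 and G2/M genes and −1.118 for DNA replication. For immune lists they were −4.459 (B and plasma cell), −3.64 (T and NK cell), −2.887 (MHC class II), −1.454 (macrophage and monocyte), −1.393 (mast cell), −1.017 (neutrophil), −1.673 (interferon response), −1.166 (NF-kB inflammation) and −0.745 (SASP). They were −1.108 for endothelial, −2.32 for white adipocyte, −0.543 for fatty acid oxidation and −0.641 for immediate early and dissection stress genes. They were positive for the proteasome (0.288), oxidative phosphorylation (0.161), fast skeletal muscle (0.4) and glycolysis (0.448).

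The FOXM1 and G2/M list was lower in dNdK aorta, and over the 6 libraries its score followed the B and plasma cell score (Pearson r 0.943, exact permutation p = 0.00833, adjusted 0.025 over 3 relations; Spearman rho 0.943, p = 0.0167, adjusted 0.0501; r 0.954 without Rosa26 2 and 4). Depth alone did not remove the difference. With every library thinned to the depth of the smallest, 3919526 counts, the median was −1.363 over the 23 members still measured (40 in the full data). The SE of the members, 0.219, takes them as independent, and is too small since their estimated correlation was 0.634. RNA of dividing B and T cells in the Rosa26 libraries may be the source: the difference in score was −1.229 (SE 0.704) without a covariate, −0.639 (SE 0.129, 95% interval −1.049 to −0.229) with the B cell score and −0.496 (SE 0.268, −1.347 to 0.356) with the T cell score, so the data cannot settle it. In the same order the differences were −1.555 (SE 0.692), −1.062 (SE 0.47) and −0.965 (SE 0.565) for MHC class II and −1.09 (SE 0.315), −1.009 (SE 0.376, −2.204 to 0.187) and −0.976 (SE 0.39, −2.216 to 0.265) for mast cells, where both lists stayed called with each score (adjusted p up to 0.022 and 0.0168) but the intervals with each score reach 0, so lymphocyte RNA stays open for both, with the mast cell difference the less changed. An effect of the genotype on immune cells or on dividing cells of the vessel stays open and was not tested apart from tissue make-up.

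The white adipocyte list was higher in dNdK muscle, and adipose tissue left on dNdK library 3 is a candidate source. Without that library the median was 0.139 and the list was not called (adjusted p = 0.938, range over 14 alternatives 1.69e-12 to 0.968). Carry-over from aorta dNdK 1, whose table ends in the same number, would bring abundant aorta genes at 1 constant fraction. Over 34 such genes the fraction ran from 3.83% to 44.7%, a ratio of 11.7, which argues against it. Fat within the muscle of that animal, as a trait of the animal or of the genotype, was not tested and stays open.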

How the results depend on the processing

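The alternatives with libraries left out in pairs or threes, with cell type scores as covariates, without on-or-off genes and with the earlier quasi-likelihood of edgeR were chosen after seeing the data. The last of these gave the same gene counts as the main fits (713 aorta and 792 muscle genes at an unadjusted p under 0.05), so it tests nothing further. The exclusion of sex-linked genes was not run, since none of the 6 is among the genes used here. Where a group kept 1 library, that library was taken to vary like the others. Depth limited the low genes: 0 to 3 counts of Foxm1 in muscle cannot show a difference, and at 2-fold the simulated aorta design called 3.39% of changed genes. In all cases below where libraries were not left out, the cause was not tested.

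Aorta genes called (1 in the report) were 13 with DESeq2, 0 with the counts of the first strand, 0 with those of the second strand, 0 with all 13 libraries in 1 fit, and 0 to 1 with a library left out in turn (0 without Rosa26 1, Rosa26 2 or dNdK 1, and without dNdK 2 the gene called was Cops8). Without Rosa26 1 and 2 the count was 264 (191 higher, 73 lower), and without the 3 libraries with heart RNA 30 (29 higher, 1 lower). Muscle genes called (0 by edgeR, 792 at an unadjusted p under 0.05) were 7 with DESeq2, 0 to 3 with a library left out in turn (3 without dNdK 1) and 6 without dNdK 1 and 3. Genes that differed between the tissues (0 by edgeR, 1044 at an unadjusted p under 0.05) were 6 with DESeq2 and 0 with the file number, which may mark the animal, as a random block (correlation 0.301). With that block, tried for lists only after the results were seen, 18 of the 19 lists kept their call in camera on the moderated t of limma-voom, where 17 did without it, and the neutrophil list did not (adjusted p = 0.0985).

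Lists called in aorta (15) were 8 without the heart RNA libraries, 7 with the B cell score, 8 with the T cell score, and 0 with an estimated correlation and 0 with fry. Lists called in muscle (10) were 6 with a min.count of 50, 17 with the adipocyte score, 0 with an estimated correlation and 0 with fry, and 6 to 15 with a library left out in turn (6 without Rosa26 2).

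The numbers in the titles do not pair the samples: the correlation of residuals within a number was −0.35 and 0.19 in aorta and 0.21, −0.043 and −0.0077 in muscle. With a block on that number 163 aorta genes were called (19 higher, 144 lower), the endothelial list in aorta had a median of 0.043, the immediate early list −0.004 with a positive test, and Cdkn1a in muscle −0.019. With voom quality weights Cdkn1a in muscle was at −0.45.

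Directions turned for some values. In aorta Mki67 was at 0.182 without Rosa26 1 and 2, 0.264 without the heart RNA libraries, 0.552 with the B cell score and 0.906 with the T cell score. With the T cell score Blk was at 0.1, Pax5 at 0.176, the T and NK cell list at 0.136 and the B and plasma cell list at 0.301. That B and plasma cell list had a positive test but medians of −0.844 without Rosa26 1 and 2 and −0.454 without the heart RNA libraries. In muscle without dNdK 1 and 3, values were −0.765 for Ccl8, −2.073 for Cdkn1a, −0.562 for Fas, −1.251 for Top2a, −0.068 for Adgre1, −0.46 for Jchain, −0.068 for Mzb1 and −0.831 for Vcam1. The list medians there were −0.13 for FOXM1 and G2/M, −0.341 for interferon response, −0.108 for NF-kB inflammation and −2.14 for B and plasma cell. With a muscle library left out in turn, Cdkn1a ran from −0.476 to 1.06 and Mzb1 from −0.153 to 3.916 (both lowest without dNdK 1). Thrsp ran from −0.194 to 5.167 and the white adipocyte list from 0.139, with a negative test, to 3.225 (both lowest without dNdK 3). With the adipocyte score Cdkn2c was at −0.117, Thrsp at −0.008 and the white adipocyte list at −0.001.

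Other splits of the libraries were also counted. In muscle the real split calls 0 genes, which all 35 splits reach (highest other 8), so that count says nothing. Of the 35, 11 call at least the real 10 lists (highest other 14), so chance cannot be excluded for the muscle lists. The 15 aorta splits are too few for a share under 0.05: 5 gave at least the real 15 lists (highest other 21). Setting Rosa26 3 and 4 against the other 4 aorta libraries called 1012 genes against the real 1. This points to a structure of the samples apart from genotype, whose cause was not tested. Unmapped reads were 7.21% and 7.449% in Rosa26 3 and 4, against 4.621% to 5.622% in the other 4. The share on the first strand was 46.34% and 46.37% there, against 48.39% to 49.33% in the other 4. Leaving out Rosa26 1 and 2 keeps only Rosa26 3 and 4 as controls, so its results do not test lymphocyte RNA alone.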

Other observations

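Some gene groups with a part in aging vessels and muscle were measured without a call. In aorta the smooth muscle contractile list had 27 measured members (camera adjusted p = 0.709, test positive but median −0.07), the extracellular matrix list 39 (median −0.22, adjusted p = 0.271), the osteochondrogenic and calcification list 19 (median −0.55, adjusted p = 0.101), the fibroblast list 23 (median −0.32, adjusted p = 0.171) and the DNA repair list 42 (adjusted p = 0.906). In muscle the extracellular matrix list had a median of −0.12 (adjusted p = 0.0586), the antioxidant and NRF2 list 0.42 (adjusted p = 0.0663), the satellite cell and myogenesis list −0.14 (adjusted p = 0.147), the atrophy and autophagy list −0.02 (adjusted p = 0.889) and the slow skeletal muscle list 0.08 (adjusted p = 0.779). A p above the threshold does not show that these groups were alike.

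The tests on genes that were on or off in single libraries were chosen only after the results were seen. The number that ends each deposited table's name recurs in both tissues for 4 numbers, and 13 genes had a gap of at least 3 log2 units between libraries in both tissues. Under the pairing by number 46 of 52 states matched between the tissues, against at most 42 under the other 23 of 24 pairings (exact permutation p = 0.0417, the smallest these pairings can give). For 11 of the 13 genes, among them Degs1, Abcc9, Cited2 and Sdhaf2, all 4 numbers matched. A variant carried by the animal, under a primer or in the gene, may therefore turn these genes on or off in this mixed background. Loss of an amplicon in single libraries would give matches near the median pairing, 26 of 52. The 46 lay above that, but another pairing reached 42. The 13 genes were picked from these data and lie on 8 chromosomes, so their states are not independent. The values thus argue only weakly against such loss. H2-Aa stood at 160 CPM in aorta Rosa26 3 and 13.9 CPM in muscle Rosa26 1, which share the number 50, against at most 1.37 CPM elsewhere.

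Ube2ql1 lies 2.52 Mb from Rsl1 and 2.09 Mb from Zfp729b on chromosome 13, and all 3 were higher in both dNdK aorta libraries. A chromosome 13 segment that these animals share could account for it. In muscle Zfp729b was on in Rosa26 2 and dNdK 3, where Ube2ql1 stood at 2.55 and 5.7 CPM, against 0.807 to 2.63 CPM in the other 5 libraries. The lower value lies within counting error of the highest of the others, so a shared segment and an effect of the genotype cannot be told apart. Muscle dNdK 3 also held adipocyte RNA, and Ube2ql1 stood at 75.7 and 70.1 CPM in aorta dNdK 1 and 2. The 5.7 CPM of Ube2ql1 in muscle dNdK 3 can thus not be set apart from that make-up.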
